A study of Mus musculus with 4 samples.

How the data were processed

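The series profiled N6-methyladenosine (m6A), a methyl mark on RNA, in mouse cerebral cortex by methylated RNA immunoprecipitation sequencing, in which RNA fragments are pulled down with an antibody against m6A and sequenced. Per the labels, total RNA was extracted with TRIzol from the cortex of mice after a sham procedure or after repetitive mild traumatic brain injury (rmTBI), and all 4 libraries carry the same anti-m6A antibody. The labels number the libraries 0 and 1 within each group and do not say whether they came from separate mice. P-values of the tests per peak therefore measure only the spread between these libraries, which may be technical. P-values of the gene lists at a preset correlation measure the spread among genes, and those of the Fisher and binomial tests treat peaks as units. Neither kind measures the spread between mice. The injury protocol, the time after injury and the number of mice are not given in the sources used here. No library labelled as RNA without the antibody was analysed here, nor was the METTL3 inhibitor experiment that the series description mentions.

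The submitters' processing notes name STAR, DESeq2 and the GRCm39 build without versions or roles, and the peak caller, the read counter and its use of strand are not given in the sources used here. The authors deposited 1 table of peaks, with whole-number read counts per peak in each library that are not normalized, and lists taken from it. Per the file headers, each peak belongs to a set called in rmTBI (16034 peaks) or a set called in sham (17943 peaks), so that peaks were called per condition and stacked into 33977 rows. Peak numbers reach 28375 in the rmTBI set and 28022 in the sham set, and the rows used here are therefore part of the numbered peaks. On the same strand, 67.8% of the peaks overlapped another by at least 1 base, and the rows formed 21845 overlap clusters (bedtools 2.31.1). Overlapping rows share reads and are not independent, and genes that overlap one another or have an antisense partner are uncertain.

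Of the peaks, 31971 belonged to a gene with 1 span in the RefSeq table of GRCm38.p6, and 98.3% of these overlapped that span, so that the coordinates given here are those of the deposited table read as GRCm38 positions, although the processing notes name GRCm39. The deposited table classes each peak as cds, utr3, utr5 or NP_exon. The last class is not defined in the sources used here and stood for lncRNA in the tests; it held 1245 peaks of 683 genes, of which 364 were in RefSeq lncRNA genes, 848 were in genes without a RefSeq match and 13 were in protein-coding genes. Gene symbols matched RefSeq directly for 9537 of 10415 genes and through a synonym for 297.

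The authors deposited a log2 fold change per peak, with a p-value and an adjusted p-value, from a test that is not named. Set against the counts with 0.5 added, that log2 value followed the ratio of rmTBI library 1 to rmTBI library 0 over the ratio of sham library 1 to sham library 0 (Pearson r = 0.99 across peaks, which are not independent replicates), and 95.7% of the peaks lay within 0.1 of it after the median offset of 0.07. It did not follow the mean of the rmTBI libraries over the mean of the sham libraries (r = -0.29). The deposited values are therefore reported apart from the test of rmTBI against sham. The deposited list of differing peaks breaks off in its last row and held 324 peaks, the 277 higher and 47 of the 146 lower ones, so the separate lists of higher and lower peaks were used.

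Groups were taken from the labels, 2 sham and 2 rmTBI libraries. Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr, the quasi-likelihood F-test and Benjamini-Hochberg adjustment over 33415 peaks, on 2 residual degrees of freedom before the spread was shared across peaks. Peaks with an adjusted p under 0.05 were called. The standard error (SE) of a log2 fold change was its size divided by the square root of F. Levels are TMM-scaled CPM as given by the cpm function of edgeR. Gene lists fixed before the data were examined (19 lists, 18 with at least 3 genes measured) were tested with camera in limma 3.58.1 on each gene's median log2 CPM over its peaks, with a prior count of 2 and a preset correlation of 0.01, and again with an estimated correlation. Camera takes its degrees of freedom from the number of genes in the first run and from the libraries (2 residual) in the second. Few lists could pass the second run, so a failure there does not show that correlation between genes explains a shift. Fisher's exact tests and binomial tests were two-sided and run in SciPy 1.17.1. For the deposited log2 values, each list's median was ranked among 10000 random lists matched on level. Library totals over the peaks were 14437317 counts for sham library 0, 26356562 for sham library 1, 13753600 for rmTBI library 0 and 26888072 for rmTBI library 1.

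On data simulated from these counts for rmTBI against sham, with 100 peaks changed by each fold, the test recovered 83% of the peaks changed 4-fold and 9% of those changed 2-fold, with 4 false calls among 33040 peaks. With the number as a block, on data simulated with the spread left by the block, 92% and 64% were recovered, with 13 false calls. Neither simulation held a difference between the numbers such as these libraries show, so recovery and false calls on the real counts may differ. On a simulated matrix of 5000 genes drawn independently, camera recovered the 1 shifted list and called 0 of 19 others. That does not show how it behaves on correlated genes, and the estimated correlation reached 0.33 for the immediate early genes. Alternatives set before the data were examined were library-size scaling, DESeq2 1.42.0, other count filters, leaving out each library, the replicate number as a block, peak width, the sex chromosomes and mitochondrial genome left out, 1 peak per gene and other thresholds. Each condition's peaks alone, 1 peak per overlap cluster, and the class test on the deposited lists were chosen after seeing the data. Genes were named by a rule fixed beforehand, up to 12 genes and 8 lncRNA genes per direction by size of change, taken from the deposited lists where the test called fewer, and for each list its called members or the member with the smallest p-value, which for the synaptic list is not reported here. Other genes were named after their values were seen. The DRACH motif was not examined, because no genome sequence was used here.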

Results

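Read counts at m6A peaks were compared between the cortex of mice after rmTBI and after a sham procedure, with 2 anti-m6A libraries in each group. The table held 33977 peaks in 10415 genes, with a median of 108 and 209 counts per peak in sham libraries 0 and 1 and of 98 and 214 in rmTBI libraries 0 and 1. By the authors' classes, 50.4% of the peaks lay in coding sequence, 39.7% in 3' UTRs, 6.24% in 5' UTRs and 3.66% in the class NP_exon. Per the labels all 4 libraries carry the antibody, and on that reading a difference in counts at a peak does not separate the methylation of a transcript from its abundance. What the numbers 0 and 1 stand for is not given in the sources used here. If they mark different kinds of library, each mean and SD over 2 libraries mixes them. Values within each number are therefore given for the leading called genes, for the gene lists that passed, and for the lists and some of the genes whose sign turned between the numbers.

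The first question, from the series description, was which transcripts carry a different m6A signal after rmTBI. Counts fell in both rmTBI libraries at peaks of 12 genes, among them Tcf7l2, Slc17a6, Shox2, Lhx9 and Ntng1, which are known from thalamic or other subcortical neurons. Tnnt1, which encodes a troponin T, fell from 90.1 ± 0.412 CPM in sham to 7.07 ± 0.783 CPM in rmTBI (SD, n = 2 libraries each) at a coding peak on chromosome 7 (4508527 to 4514509), a log2 fold change of -3.66 (SE 0.27, adjusted p = 0.0248, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Tcf7l2, a transcription factor of the Wnt pathway that marks thalamic excitatory neurons, fell from 139 ± 25.2 CPM to 16.1 ± 2.48 CPM at a coding peak on chromosome 19 (55910680 to 55919553; log2 -3.11, SE 0.28). Slc17a6, the vesicular glutamate transporter typical of subcortical neurons, fell from 73.0 ± 12.3 CPM to 13.8 ± 2.21 CPM at a 3' UTR peak on chromosome 7 (51669050 to 51669411; log2 -2.40, SE 0.28). For Shox2, a homeobox gene of the thalamus, a 3' UTR peak on chromosome 3 (66972680 to 66973576) held 46.6 and 86.2 CPM in the sham libraries and 0.303 and 1.76 CPM in the rmTBI libraries (log2 -5.84, SE 0.66).

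The other genes called lower included Lhx9, a LIM homeobox gene of the developing thalamus (log2 -2.97, SE 0.34), and Ntng1, which encodes netrin-G1 on thalamocortical axons (log2 -2.07, SE 0.24). Synpo2 and Nexn encode actin-binding proteins. Synpo2 had 5 called peaks with log2 values from -3.48 to -3.10, and Nexn had 4 from -2.43 to -2.15, some of them overlapping peaks of the rmTBI and sham sets. Plekhg1 had 4 called peaks (log2 -2.95 to -2.61), and Tcf7l2 had 4 (log2 -3.17 to -2.59). Slitrk6, which encodes a neuronal transmembrane protein (log2 -3.63, SE 0.42), and F5, the gene of coagulation factor V (log2 -3.75, SE 0.37), had 1 called peak each. All 29 called peaks lay lower in both rmTBI libraries than in both sham libraries. Within the libraries numbered 0 the log2 fold was -3.76 for Tnnt1, -3.13 for Tcf7l2 and -2.39 for Slc17a6, and within those numbered 1 it was -3.55, -3.07 and -2.41.

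**Figure D1:**
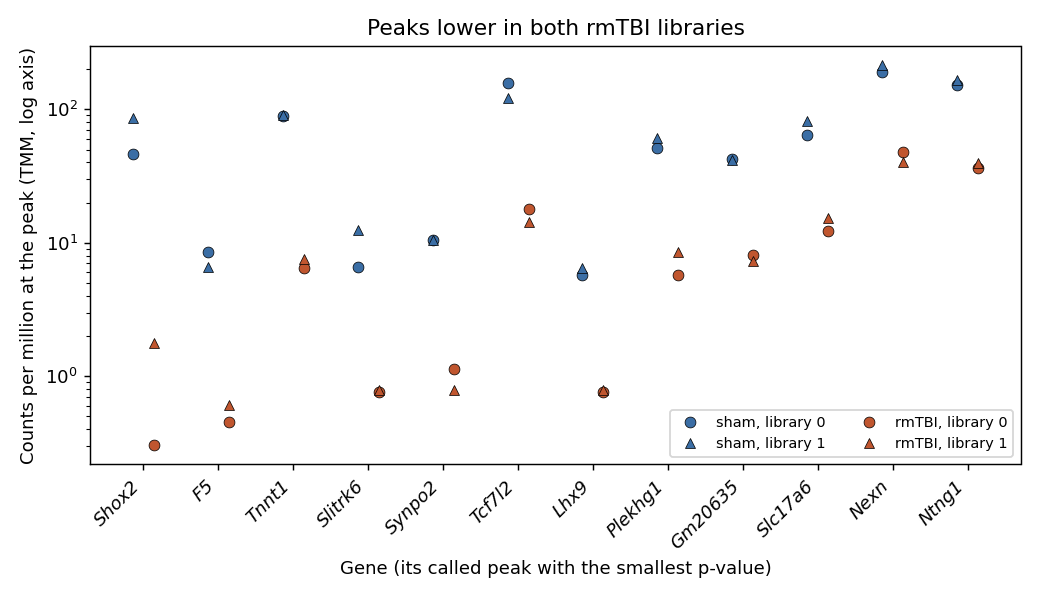
TMM-scaled CPM (log axis) at 1 called peak of each of the 12 genes (x axis) in each library, with sham in blue, rmTBI in orange, circles for library 0 and triangles for library 1. Both rmTBI libraries lie below both sham libraries at every peak drawn, with Tnnt1 at 6.52 and 7.63 CPM in rmTBI against 89.8 and 90.3 CPM in sham.

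In all, the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, in a model of group without the label number, called 29 of 33415 peaks, 0 higher and 29 lower (exact binomial p = 3.73e-09, a description only, because overlapping peaks share reads), with adjusted p from 0.0248 to 0.0471. At an unadjusted p under 0.05 there were 948 peaks, of which 244 were higher. Neither the count nor the one-sidedness of the calls held when the label number was added to the model. The same edgeR test then called 3553 peaks, 1810 higher and 1743 lower, with all 29 among them. That model leaves fewer residual degrees of freedom than group alone. If the numbers mark kinds of library made from the same RNA, the libraries of a group are not separate samples. Its calls would then rest on no spread between samples. The count also depended on single libraries and on scaling, with 121 called peaks without sham library 0, 82 without sham library 1, 92 without rmTBI library 0 and 122 without rmTBI library 1, and all 29 remained in each. It was 2, both of Tnnt1, with library-size scaling and 0 among peaks with at least 10 counts in every library, where 855 had an unadjusted p under 0.05 by the same edgeR test and the smallest adjusted p was 0.0509. The folds at the named peaks stayed, with log2 from -5.84 to -2.08 under library-size scaling (adjusted p 0.0497 to 0.114, edgeR with Benjamini-Hochberg adjustment) and from -3.67 to -2.07 at the 10 of them that met the count minimum (adjusted p 0.0509 to 0.106). DESeq2 called 131 peaks, including all 29.

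No peak was called higher in rmTBI by edgeR with all 4 libraries and group alone in the model (244 were higher at an unadjusted p under 0.05). With a library left out, 2 to 3 were called higher. DESeq2 called 5 higher peaks, in Mef2c, Arhgap25 and Ndst4, which are named here after their values were seen. Mef2c, a transcription factor of cortical excitatory neurons, held 16.6 and 15.2 CPM in the sham libraries and 43.9 and 35.9 CPM in the rmTBI libraries at a 5' UTR peak on chromosome 13 (83504332 to 83524714), a log2 fold of 1.33 (SE 0.33, adjusted p = 0.0174, DESeq2 with Benjamini-Hochberg adjustment). With the edgeR quasi-likelihood test and Benjamini-Hochberg adjustment the same Mef2c peak had an adjusted p of 0.298, and the lowest value among the 5 peaks was 0.165 for Arhgap25, which encodes a GTPase-activating protein of Rac.

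Because several of the called genes are known from the thalamus, marker genes of brain regions were listed after these genes had been seen. The 9 thalamic markers that had not been seen before the list was written, among them Cbln1 and Gbx2, had a median gene-level log2 fold of -1.18, and all 9 lay lower in rmTBI. Their median was -1.29 within the libraries numbered 0 and -1.03 within those numbered 1. Camera with the preset correlation gave them an adjusted p of 5.36e-15, and with an estimated correlation an adjusted p = 0.0922. The latter run used only the 2 residual degrees of freedom of the libraries. The 12 cortical neuron markers not seen before had a median of 0.06, with 7 higher and 5 lower (adjusted p = 0.0854, camera). The 11 striatal markers not seen before, of which Drd2 and Adora2a lay lowest, had a median of -0.53, with 3 higher and 8 lower (adjusted p = 6.20e-05, camera, and adjusted p = 0.121 with an estimated correlation).

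The series title makes lncRNA m6A the target of the screen. Of 1201 tested NP_exon peaks in 656 genes, 2 were called, both in Gm20635, a RefSeq lncRNA gene on chromosome 5. They covered the same transcript (143391656 to 143403718), and the longer of them fell from 42.3 ± 0.482 CPM in sham to 7.69 ± 0.597 CPM in rmTBI (SD, n = 2 libraries each; log2 -2.46, SE 0.26, adjusted p = 0.0437, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Adjusted over the list alone, the NP_exon peaks gave 3 calls. The third was at Gm43398 (143395502 to 143395682; log2 -3.47, SE 0.47), a position that lies inside the called span of Gm20635, so that the 2 genes cannot be taken as separate signals without knowing how reads were assigned. Unadjusted, 31 NP_exon peaks had p under 0.05, 13 of them higher. With the label number added to the model, and with the limit given above for that model, edgeR called 98 NP_exon peaks over all peaks, 63 of them higher in rmTBI. By RefSeq biotype that model called 27 lncRNA peaks.

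Among the brain lncRNAs fixed beforehand, 13 of 55 had a peak, and 0 were called by edgeR either over all peaks or adjusted over the list alone. Dlx6os1, an antisense transcript of the interneuron gene Dlx6, had the smallest p-value of the list, with 8.51 ± 3.17 CPM in sham and 14.7 ± 3.89 CPM in rmTBI (SD, n = 2 libraries each; log2 0.78, SE 0.34, adjusted p = 1, edgeR with Benjamini-Hochberg adjustment). At gene level Tug1 had a log2 fold of -0.22 and Airn one of -0.54 (-1.48 within the libraries numbered 0 and 0.40 within those numbered 1), and the list's median was 0.04 (-0.01 and 0.12, adjusted p = 0.900, camera). Called peaks made up 0.167% of the NP_exon peaks and 0.0838% of the peaks in the coding classes (odds ratio 1.99, Fisher's exact p = 0.280). With lncRNA taken from RefSeq, 2 of 400 lncRNA peaks and 27 of 31962 protein-coding peaks were called (odds ratio 5.94, Fisher's exact p = 0.0497), where both lncRNA peaks were those of Gm20635. No coding class passed the threshold for its share of called peaks, with 19 in coding sequence, 8 in 3' UTRs and 0 in 5' UTRs (Fisher's exact adjusted p = 0.280 for each).

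The second question was whether genes of the cell types and processes affected by brain injury moved together. Genes of oligodendrocytes and myelin were lower in rmTBI for 15 of 17 measured members, with a median log2 fold of -0.70. Mbp, which encodes myelin basic protein, stood at -0.70, Mobp at -0.94 and Bcas1 at -0.79. Of the progenitor genes, Pdgfra and Gpr17 stood at 0.02 and 0.30, and Cspg4, near the lower limit of detection, at -0.18. The median was -0.71 within the libraries numbered 0 and -0.66 within those numbered 1, in the same direction as the thalamic and striatal markers. Camera gave the list an adjusted p of 4.97e-08 with the preset correlation, and an adjusted p = 0.434 with an estimated correlation. No single peak of the list was called by edgeR, and the Mobp peak with the smallest p-value had a log2 of -0.98 (SE 0.28, adjusted p = 0.908, Benjamini-Hochberg).

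Markers of the choroid plexus and ependyma lay lower for 4 of 5 measured genes (median log2 -1.83). Kl, which encodes klotho, stood at -3.03, Clic6 at -1.83 and the ciliary gene Ccdc153 at -1.28. The prolactin receptor gene Prlr stood at -2.81 and Foxj1 at 0.53 (-0.07 and 1.13 within the numbers), both near the lower limit of detection. The median was -1.76 within the libraries numbered 0 and -1.34 within those numbered 1, in the same direction as the thalamic, striatal and myelin genes. The list had an adjusted p of 1.17e-06 by camera with the preset correlation, and an adjusted p = 0.434 with an estimated correlation. None of its peaks was called over all peaks by edgeR, and 9 peaks of Kl, Clic6 and Ccdc153 were called adjusted over the list alone.

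Immediate early genes, which respond to neuronal activity, were higher in rmTBI for 14 of 19 members (median log2 0.46). Egr4, near the lower limit of detection, stood at 1.38, Egr2 at 0.89, Fosb at 0.78, Arc at 0.51 and Egr1 at 0.41, and Klf4 and Klf2 at -0.59 and -0.58. Klf4 turned from -1.94 within the libraries numbered 0 to 0.75 within those numbered 1. The median was 0.24 within the libraries numbered 0 and 0.51 within those numbered 1. The adjusted p was 0.000453 by camera with the preset correlation, and adjusted p = 0.573 with an estimated correlation. Microglial and macrophage markers were higher for 9 of 13 (median log2 0.26), with Aif1 at 0.83, Cd68 at 0.72 and C1qa at 0.61, and Cd74, near the lower limit of detection, at 1.13 (0.39 and 1.87 within the numbers), against Spp1 at -0.40, and with medians of 0.16 within the libraries numbered 0 and 0.25 within those numbered 1. Their adjusted p was 0.00409 by camera, with an adjusted p = 0.434 with an estimated correlation and 0.132 over the 8 members with at least 2 peaks. By smallest p-value the leading peaks were those of Btg2 (log2 0.89, SE 0.29) and Aif1 (log2 0.87, SE 0.30). In neither list was a peak called by edgeR over all peaks or adjusted over the list alone.

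Synaptic genes were higher for 32 of 41 members but by a median log2 of 0.09 (adjusted p = 0.0797, camera). The list passed the threshold when each gene was taken at its peak with the smallest p-value (median log2 0.23, adjusted p = 0.0208), a choice that favours a call. It had an adjusted p = 0.354 with an estimated correlation. It also passed with each peak as its own unit (median log2 0.10, adjusted p = 0.00252, and adjusted p = 0.312 with an estimated correlation). With the label number as a block the list passed as well (adjusted p = 0.0133 by camera, and adjusted p = 0.686 with an estimated correlation). Neuronal identity markers moved both ways, 12 higher and 10 lower (median log2 0.03, with -0.01 and 0.07 within the numbers, mean -0.07, direction up by camera, adjusted p = 0.983). Slc17a6 was their 1 called gene, and adjusted over the list alone Nefh, the neurofilament heavy chain gene, was called as well (log2 -1.20, SE 0.22, at its 3' UTR peak). Genes of the m6A machinery showed no shift, with 7 of 16 measured genes higher and a median log2 of -0.01 (adjusted p = 0.983, camera, direction up). The reader gene Prrc2a had the smallest p-value of that list (log2 -0.45, SE 0.39, with -0.87 and 0.07 within the numbers, adjusted p = 1, edgeR with Benjamini-Hochberg adjustment), and no peak of Mettl3, the methyltransferase that the study inhibited, was analysed here.

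The remaining lists did not pass the threshold by camera at gene level. With each peak as its own unit, interferon response genes (adjusted p = 0.0257, and adjusted p = 0.637 with an estimated correlation) and oxidative stress genes (adjusted p = 0.0130, and adjusted p = 0.425 with an estimated correlation) passed. At gene level, interferon response genes had a median log2 of 0.17 (0.46 within the libraries numbered 0 and 0.05 within those numbered 1, adjusted p = 0.0797), with Gbp3 at a peak log2 of 0.58 (SE 0.26). Astrocyte and gliosis markers had a median of -0.03 and a mean of 0.06 (medians of 0.08 and 0.01 within the numbers, direction up, adjusted p = 0.875), with Serpina3n, an acute-phase gene of reactive astrocytes, at a peak log2 of 1.06 (SE 0.37). Inflammatory genes had a median of -0.10 (-0.21 within the libraries numbered 0 and 0.31 within those numbered 1, adjusted p = 0.875), apoptosis genes -0.13 (0.354), axon guidance genes 0.10 (0.174), tau and amyloid genes 0.01 (0.900, with -0.03 and 0.04 within the numbers), oxidative stress genes -0.22 (0.168), vascular markers -0.15 (0.172) and long neuronal genes 0.07 (0.295). The members with the smallest p-values in these lists were Traf6 (peak log2 -0.35), Fadd (-0.50), Plxna2 (0.63), Bin1 (-0.70), Tfam (-0.38), Plvap (-1.27) and Dmd (0.59), and none was called by edgeR. Meningeal fibroblast markers had a median of 0.28 (0.52 within the libraries numbered 0 and 0.04 within those numbered 1, adjusted p = 0.174). Adjusted over that list alone, edgeR called Col6a1, a collagen gene, higher (log2 1.19, SE 0.25) and Igf2 lower (adjusted p = 0.0450 over the list), and neither passed over all peaks. None of the 15 blood cell markers had a peak.

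**Figure D2:**
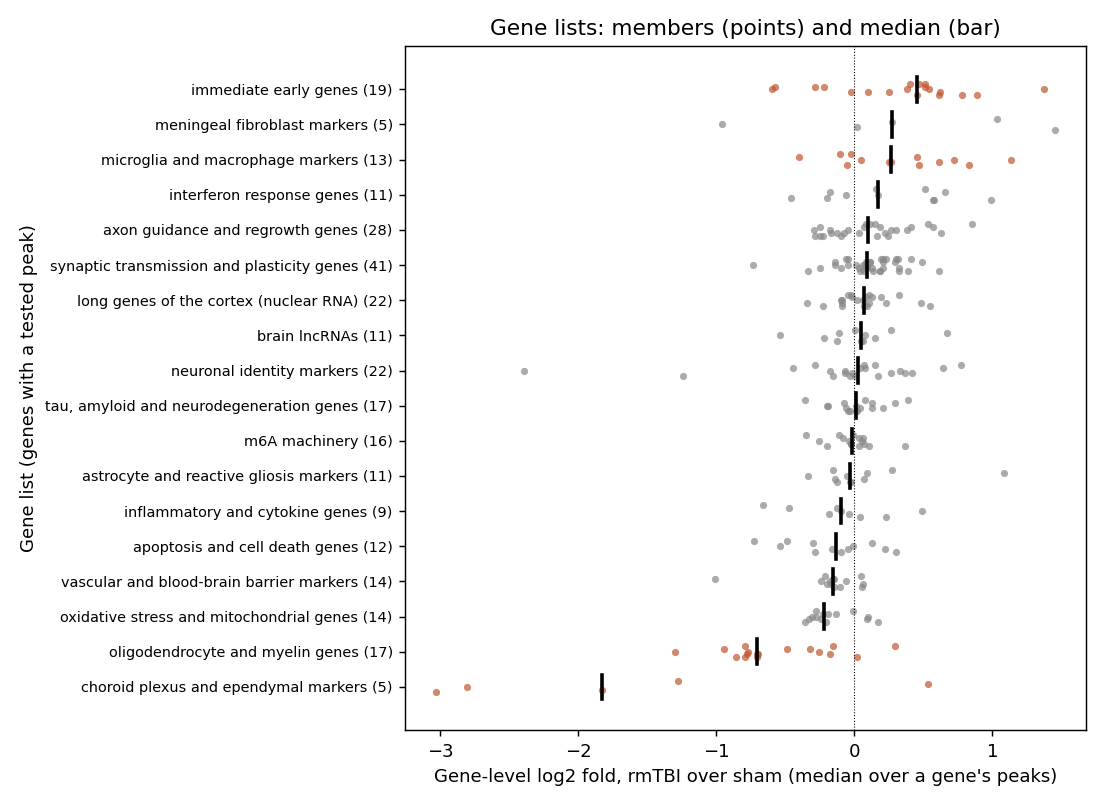
Gene-level log2 fold of rmTBI over sham (x axis, the median over a gene's peaks) for the members of 18 gene lists (points, with the number of measured genes in brackets) and each list's median (black bar). Lists with a camera adjusted p under 0.05 at the preset correlation are orange, from choroid plexus markers at a median of -1.83 to immediate early genes at 0.46. With an estimated correlation, a run on 2 residual degrees of freedom that few lists could pass, 0 of the 18 lists passed.

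The authors' deposited table gave its own contrast, which followed the ratio of library 1 to library 0 in rmTBI over that in sham. It listed 277 peaks of 237 genes as higher and 146 peaks of 129 genes as lower, which are exactly the peaks with p under 0.05 and an absolute log2 of at least 1 in the authors' deposited table. Among the genes with the largest listed increase were Mmp17, a matrix metalloproteinase gene (deposited log2 6.06 at a 3' UTR peak on chromosome 5, 129608440 to 129608590), Klf4, a zinc finger transcription factor gene (5.46, coding, chromosome 4, 55530020 to 55530200), and Cspg4, the NG2 proteoglycan gene of oligodendrocyte progenitors (5.32, coding, chromosome 9, 56885874 to 56886204), in the authors' deposited table. Each deposited peak named in this paragraph and the next had an adjusted p of 0.998 by the authors' unnamed test. The Mmp17 peak held 20 and 2 counts in rmTBI libraries 1 and 0 and 2 and 14 in sham libraries 1 and 0. The Klf4 peak held 36 and 0 counts in rmTBI libraries 1 and 0 and 14 and 18 in sham libraries 1 and 0. The Cspg4 peak held 28 and 2 counts in rmTBI and 10 and 30 in sham, in the same order. AU041133, Thg1l, Slc26a1, Jmy, Tmem168, Rad50, Zfp951, H13 and Zfp438 had values from 5.63 to 4.65 in the authors' deposited table.

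Among the largest decreases in the authors' deposited table were Tha1 (log2 -6.70, 3' UTR, chromosome 11, 117867951 to 117868102), the monocarboxylate transporter gene Slc16a14 (-5.51, 5' UTR, chromosome 1, 84934953 to 84935134) and Npsr1, the neuropeptide S receptor gene (-4.83, 3' UTR, chromosome 9, 24314308 to 24314548). Slc16a14 held 16 and 24 counts in rmTBI libraries 1 and 0 and 29 and 0 in sham libraries 1 and 0. Tha1 held 2 and 11 counts in rmTBI and 18 and 0 in sham, in the same order. Tbcc, Ccdc40, Plekhm1, Zfpm1, Slc24a1, Nifk, Usp40, Zfp995 and Zfp839 had values from -5.44 to -4.19 in the authors' deposited table. Of the listed lncRNA peaks, Kcnmb4os2 (2.68), Tug1 (2.59) and Airn (2.05) were higher and Cep112it (-1.65) lower in the authors' deposited table, and the Tug1 peak held 55 and 7 counts in rmTBI libraries 1 and 0 and 41 and 33 in sham libraries 1 and 0. Transcripts without a descriptive name were Gm43292 (5.20), Gm2415 (3.93), Gm43426 (2.86), 2510017J16Rik (2.78) and Gm38250 (2.74) among the higher, and Gm6658 (-3.40), 2600014E21Rik (-3.39), 9530086O07Rik (-2.07), 5430434F05Rik (-1.55), 8430422M14Rik (-1.35), Gm44831 (-1.14) and Gm20371 (-1.14) among the lower, in the authors' deposited table.

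At the higher-list peaks the median was 9 counts in rmTBI library 0 against 34 in sham library 0, and 57 in rmTBI library 1 against 47 in sham library 1. At the lower-list peaks it was 32 in rmTBI library 0 against 10 in sham library 0, and 41.5 in rmTBI library 1 against 51 in sham library 1. A p under 0.05 was given to 560 peaks (1.65%) in the authors' deposited table, where a uniform p would put 1699 there, and 3 peaks had an adjusted p under 0.05. These were the Shox2 peak named above and 2 overlapping coding peaks of Synpo2, all of them called lower in rmTBI by the count test. Shox2 stands among the higher peaks at a log2 of 1.70 in the authors' deposited table, with 49 and 4 counts in rmTBI libraries 1 and 0 against 2356 and 654 in sham libraries 1 and 0. It was the only one of the 29 called peaks in either list, and 18 of the 29 had a log2 above 0 in the authors' deposited table.

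**Figure D3:**
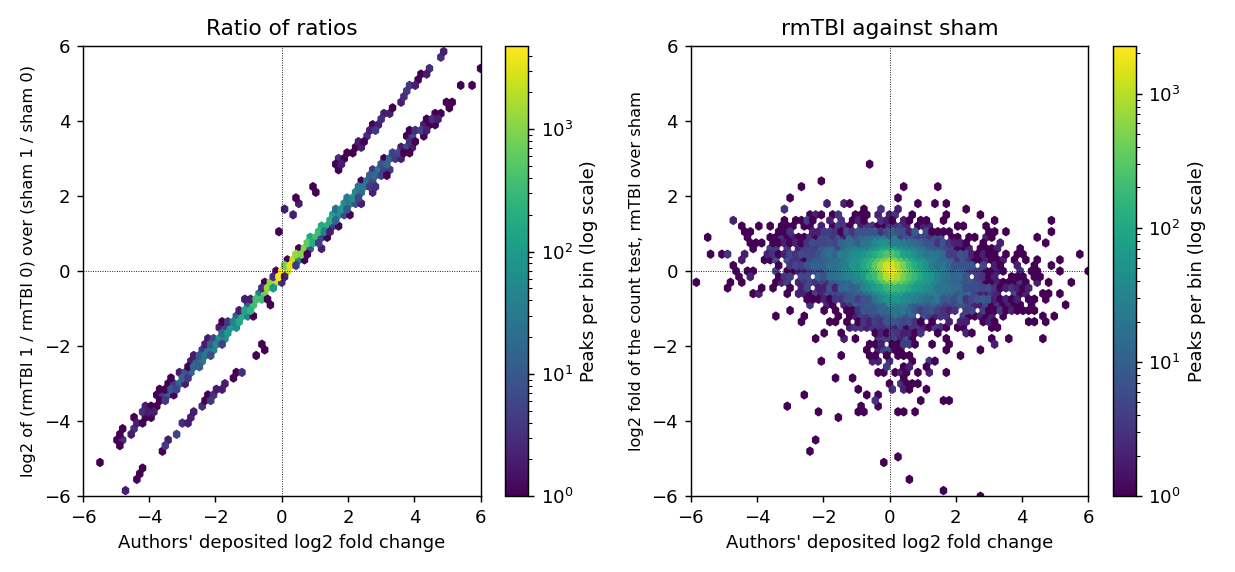
The authors' deposited log2 fold change (x axis) against the log2 ratio of library 1 to library 0 in rmTBI over that in sham, centred on its median (left), and against the log2 fold of rmTBI over sham from the count test (right), for 33415 peaks with colour for peaks per bin on a log scale. The left panel follows the diagonal, apart from short parallel lines, and the right panel does not; 7 peaks lie outside the axes.

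By position, the listed peaks of the authors' deposited table made up 0.859% of the coding-sequence peaks and 1.64% of the other peaks (odds ratio 0.52, Fisher's exact adjusted p = 3.09e-10), 1.58% of the 3' UTR peaks (odds ratio 1.55, adjusted p = 2.01e-05, Fisher's exact test), 1.89% of the 5' UTR peaks (odds ratio 1.58, adjusted p = 0.0112, Fisher's exact test) and 1.85% of the NP_exon peaks (odds ratio 1.52, adjusted p = 0.0661, Fisher's exact test). Taken apart, NP_exon peaks passed in the lower list (odds ratio 2.15, adjusted p = 0.0308, Fisher's exact test) and not in the higher one (1.19, adjusted p = 0.519). So did 5' UTR peaks (2.12, adjusted p = 0.0106, against 1.30, adjusted p = 0.346, Fisher's exact test). The 3' UTR peaks passed in the higher list (1.65, adjusted p = 6.80e-05) and not in the lower one (1.36, adjusted p = 0.0627, Fisher's exact test). The difference between the lists was not tested. Coding-sequence peaks were fewer in both (odds ratios 0.545 and 0.481, adjusted p = 3.57e-06 and 8.17e-05, Fisher's exact test). All of these p-values are descriptions only, because overlapping rows share reads. Of the listed peaks, 142 overlapped a peak of the other condition's set, and 80 of these had an overlapping peak also listed. No repeat with 1 peak per gene was run. Listed peaks also had lower median counts than all peaks in each library, and position was not set apart from depth. Of the genes in the fixed lists, Airn, Tug1, Cspg4, Klf4 and Prlr had peaks in the higher list alone, Grin1, Ifit1 and Sema3f in the lower list alone, and Cp in both. No list's median in the authors' deposited table lay outside the random lists after adjustment over the 18 lists, where the smallest adjusted p was 0.392 for interferon response genes (median log2 -0.33) and for oxidative stress genes (median log2 0.23).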

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

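The count tests on each condition's peaks alone and on 1 peak per overlap cluster, and the class and RefSeq tests on the authors' lists, were chosen only after the data were seen. In the counts of calls below, lncRNA stands for the class NP_exon, where 848 of 1245 peaks had no RefSeq match. By RefSeq biotype the called lncRNA peaks were 2 in the count test, 2 with DESeq2 and 27 with the replicate block. Of the 29 called peaks (2 of them lncRNA), all were also called by DESeq2 (131 peaks, 4 lncRNA), without each library in turn (82 to 122 peaks, 4 to 5 lncRNA; the lone library was assumed to vary like the other group) and with the replicate block (3553 peaks, 98 lncRNA; 1810 higher and 1743 lower). By library these counts were 121 without sham library 0, 82 without sham library 1, 92 without rmTBI library 0 and 122 without rmTBI library 1. Library-size scaling left 2 peaks and 0 lncRNA peaks, with adjusted p up to 0.114 at the 12 named peaks. With at least 10 counts in every library, edgeR called 0 peaks and 0 lncRNA peaks, with 855 at an unadjusted p under 0.05. Among the peaks of at least the median width it called 0 and 0, with 424 unadjusted, and the narrower peaks gave 49. DESeq2 was not run on these subsets. None of the 12 named peaks changed direction in any setting run, and the cause of the lost calls was not tested.

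With fewer peaks tested by construction, there were 14 calls (1 lncRNA) at 1 peak per gene by either choice of peak (the smallest p favours calls), 17 (1 lncRNA) among the peaks called in rmTBI, 27 (2 lncRNA) among those called in sham and 17 (1 lncRNA) at 1 peak per overlap cluster. Looser thresholds gave 51 at an adjusted p under 0.1, 948 (31 lncRNA) at an unadjusted p under 0.05, 461 (20 lncRNA) with an absolute log2 of at least 1 as well, and 3243 (165 lncRNA) by an absolute log2 of at least 0.58 alone. By RefSeq biotype 15 of the 948, 11 of the 461 and 60 of the 3243 were lncRNA peaks.

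The share of called peaks that were higher was 0% in the count test and with library-size scaling, where 2 peaks could not pass a binomial test (p = 0.5), and 50.9% with the replicate block, so that neither the small count nor its one-sidedness held there. No label says what the number stands for, and with 2 of each the samples share only a number in the design, although the data parted by it. The difference between numbers 1 and 0 in rmTBI correlated with that in sham (r = 0.48 across peaks), and libraries with the same number correlated at 0.968 and 0.980 against 0.965 and 0.962 within groups. The first principal component (53.1%) parted the numbers and the second (32.5%) the groups.

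With lncRNA taken as the class NP_exon, the odds ratio was 1.99 in the count test, 1.33 with 1 peak per gene (Fisher's exact p = 0.548) and 1.52 in the authors' deposited lists. By RefSeq biotype it was 5.94 in the count test, which rested on 2 called peaks of 1 gene, Gm20635, and 1.97 in the authors' deposited lists. For the classes, where none passed among the calls, the deposited lists, which follow another contrast, had odds ratios of 0.52 for coding sequence, 1.55 for 3' UTRs and 1.58 for 5' UTRs. The authors' deposited lists of 423 peaks shrank to 58 at p under 0.01, 2 at p under 0.001 and 3 with Benjamini-Hochberg adjustment recomputed. Of the 18 gene lists 4 passed by camera, 5 with the replicate block (synaptic genes as well, adjusted p = 0.0133), 7 with each peak as its own unit and 0 with an estimated correlation. For the myelin and microglial lists the estimated correlation (0.0048 and -0.074) lay below the preset 0.01, which argues against a higher correlation as what removed those calls. For the choroid plexus and immediate early lists it lay above (0.32 and 0.33). With an estimated correlation camera also uses the 2 residual degrees of freedom of the libraries in place of the number of genes. A small p-value is then hard to reach whatever the correlation. How much of the change came from the correlation itself was not tested. Not run were the DRACH motif, other ways to class a peak by position, and alternatives for values that are not counts. Depth limits the Shox2 and F5 peaks, which had under 10 counts in rmTBI library 0 and were not among the peaks tested at that minimum.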

Other observations

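The tests of m6A loss with the RNA kept, of a general loss of neuronal RNA, of less tissue from below the cortex and of 2 kinds of library, and the lists of region markers, were chosen only after the result was seen. Beyond the thalamus, marker genes of striatal neurons lay lower in rmTBI, with Drd2 at a gene-level log2 fold of -1.32, Adora2a at -1.28 and Penk at -0.85, while Pdyn stood at 0.33. The median of 14 genes was -0.81 (adjusted p = 8.43e-08 by camera, and adjusted p = 0.0922 with an estimated correlation). Of these, 3 had been seen before the list was written: Penk, Ppp1r1b and Pde10a. The 11 striatal genes not seen before had a median of -0.53 (adjusted p = 6.20e-05, and 0.121 with an estimated correlation). The 7 hippocampal markers went both ways, from Dsp at -2.15, near the lower limit of detection, to Wfs1 at 0.38 (median -0.28, adjusted p = 0.000501 with Prox1, which had been seen before, at -1.78 among them, and 0.120 with an estimated correlation), and the 6 not seen before had a median of -0.25 (SD 1.03) and no test of their own. Cortical markers had a median of 0.33 over 19 genes (adjusted p = 4.65e-05, and 0.215 with an estimated correlation), which rested on the 7 seen before: the 12 not seen before had a median of 0.06 (adjusted p = 0.0854), 7 higher and 5 lower, with Tbr1 at 0.89 and Rorb at -0.53.

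Peaks of genes that mark thalamic neurons, such as Tnnt1, Tcf7l2 and Slc17a6, held fewer counts in both rmTBI libraries. As the cause, a general loss of neuronal RNA was argued against by the 12 cortical markers not seen before (3, Cux2, Neurod6 and Slc17a7, shared with the fixed lists), whose median log2 of 0.0614 (SD 0.389) lay above the -1.18 (SD 0.590) of the thalamic ones by more than both spreads, a gap that scaling does not move. Less thalamic tissue in the rmTBI samples may account for the pattern, since the 9 thalamic markers not seen before (of 15 listed, none shared with the fixed lists) had a median of -1.03 in the weaker of the 2 numbers, and the most abundant of them, Calb2, stood at -0.84. Less tissue from below the cortex as a whole, which might also lower the myelin (-0.70) and choroid plexus (-1.83) lists, stays open, because the striatal markers not seen before had a median of -0.49 in the weaker number but 2 of 11, Pdyn and Isl1, lay higher in both. Loss of m6A with the RNA kept cannot be told apart from lower abundance, because the median deposited log2 of the called peaks, 0.0710, isolates m6A only if 1 number marks libraries without the antibody, and all 4 are labelled with it; an effect of the injury on thalamic neurons stays open and was not tested.

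The libraries differed more by their number than by their group: parting them by number called 5485 peaks, by group 29 and by the crossed pairs 0 (edgeR, with 131 at an unadjusted p under 0.05; DESeq2 was not run on this split). The count by number points to a structure of the samples. With 4 libraries there are 3 such splits, too few for a share under 0.05. The lower depth of the libraries numbered 0 was argued against, since 93.4% of that count was left after thinning to equal depth (5123 peaks). That 2 kinds of library were made from the same RNA may be the source, since the biological coefficient of variation was 0.0648 with the number in the model and 0.249 without it. A batch would lower that spread as well. The authors' deposited log2, however, also set library 1 over library 0 within each group (Pearson r = 0.99 across peaks). That use goes with 2 kinds of library, whereas the labels give all 4 the same antibody, so what the number stands for stays open.

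For the authors' contrast, 3909 peaks had a ratio of ratios of at least 2-fold either way, and 100 Poisson draws gave at most 1500. Among the 21136 peaks with a mean count of at least 100 there were 103 such peaks against at most 10 in the draws. These values argue against Poisson counting noise alone. Separate libraries spread beyond counting noise in any case, so that this excess does not tell counting noise with variation between library preparations from an effect of rmTBI on m6A. Both stay open, since 4 libraries leave no spread to test that ratio against.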
